A study of Mus musculus with 15 samples.

How the data were processed

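Total RNA from primary hepatocytes of male C57BL/6J mice was measured on 15 Affymetrix mouse arrays, 3 for each of the adenoviruses FXRα1, FXRα2, FXRα3, FXRα4 and GFP. The analysis began from the deposited log2 value table, which the authors had normalized and summarised per probe set. The log base is not stated and was inferred from the range of the values, 1.93 to 13.8, which matches log2 of scanner intensities. Affymetrix Expression Console 1.1 and PLIER are credited in the submitters' processing notes without a role or an order, and background correction and normalization between arrays are not given in the sources used here. The median log2 value over probe sets was 4.98, 4.93 and 4.97 in the FXRα1 arrays, 4.96, 5.01 and 4.99 with FXRα2, 4.92, 4.97 and 4.97 with FXRα3, 5.00, 5.00 and 4.99 with FXRα4, and 4.94, 4.98 and 4.92 with GFP. The labels do not say that the replicates came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

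Of 35556 probe sets, 21218 carried 1 gene symbol in the array annotation, 1881 carried several and 12457 had no gene. Entrez identifiers matched for 21185 of those with 1 symbol, and 0 symbols needed updating. Where a gene had more than 1 probe set (1386 genes), the one with the highest mean over all arrays was kept, which left 18820 genes with no filter on dim ones. Genes without a probe set of their own were not analysed here.

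The design, the tests, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. A linear model with 5 group means was fitted to all 15 arrays with limma 3.58.1 in R 4.3.3, with moderated variances that follow the mean level. The 9 contrasts were each isoform against GFP, FXRα2 against FXRα1, FXRα4 against FXRα3, the mean of the isoforms without the insert against the mean of those with it, the mean of FXRα3 and FXRα4 against the mean of FXRα1 and FXRα2, and the interaction of both features. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes within a contrast, and genes with an adjusted p under 0.05 are said to have risen, fallen or changed. The replicate numbers were not used to pair samples, since the labels do not say what samples of one number share.

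The 26 gene lists were FXR targets, bile acid synthesis and conjugation, hepatobiliary transporters, fatty acid oxidation, ketogenesis, lipolysis and lipid droplets, fatty acid and triglyceride synthesis, cholesterol synthesis and uptake, glucose metabolism, apolipoproteins and lipoprotein metabolism, complement and coagulation, acute phase, drug and xenobiotic metabolism, amino acid catabolism and urea cycle, mitochondrial respiratory chain, hepatocyte identity, type I interferon response, ER stress and amino acid response, oxidative stress (NRF2), cell cycle, p53 response, and markers of Kupffer cells, sinusoidal endothelial cells, stellate cells and fibroblasts, cholangiocytes, and lymphocytes and neutrophils. Of 613 distinct genes in the lists, 550 were measured. Some genes are members of several lists, so list calls are not independent of each other. Lists were tested against all other genes with camera at its preset correlation of 0.01 and adjusted over the 26 lists within a contrast. Members were counted per direction with p-values adjusted over all genes and, beside that, adjusted over the list alone.

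The text could name Nr1h4, the FXR targets, Cyp7a1 and Cyp8b1 in every comparison. It could name the 10 largest changes each way with an adjusted p under 0.05 and replicates that did not overlap, passing over predicted genes, with 5 each way for the N-terminus and the interaction. For the interaction the condition on overlap was not applied, which departs from the rule as fixed. For each list that passed the text could name up to 4 members with the smallest adjusted p. Marker genes named elsewhere were chosen after their values were seen.

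Shared calls between isoforms were set beside the product of the numbers called over the number tested, and beside 100 simulations of unchanged groups against the same GFP arrays. The alternatives were no mean-variance trend, robust variances, array weights, the groups of the contrast alone, leaving out the dimmest genes in either of 2 steps (14115 or 9410 genes left), quantile normalization, centring each array on its median, every probe set tested, 16 added to the linear values, a fold minimum of 1.5, the replicate number as a block, and leaving out each array in turn. For lists they were an estimated correlation and fry, for which the p-value tests whether the genes of a list move one way on balance. The correlation was estimated from the fit without the replicate number as a block. Centring on the 75th percentile and on the mean of the genes brighter than the median gene were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9, and tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6.

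The method was tested on simulated data in which 200 of 18820 genes were changed in FXRα2 against GFP. It recovered 98% of changes of 1.5-fold and 100% of those of 2, 4 and 8-fold, and called 17 unchanged genes, 7.87% of its calls. A log2 shift of 0.3 put into 1 list was the 1 list call made, and with none shifted 0 lists were called. The genes were simulated as independent, so this did not test list calls among genes that vary together.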

Results

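Gene expression was profiled in cultured primary hepatocytes of male C57BL/6J mice, on 15 Affymetrix mouse whole-transcript arrays in 5 groups of 3. FXR (gene Nr1h4) is the nuclear receptor through which hepatocytes sense bile acids, and alternative promoters and splicing give it 4 isoforms. FXRα1 and FXRα3 carry the short MYTG insert next to the DNA-binding domain, which FXRα2 and FXRα4 lack. FXRα3 and FXRα4 have a longer N-terminus than FXRα1 and FXRα2. Each isoform group received an adenovirus for the human form of the receptor together with GFP, the control group received a GFP adenovirus, and RNA was taken 36 h after transduction. The deposited values are on a log2 scale, and the median of the 15 arrays lay between 4.92 and 5.01. The precision is limited by the number of arrays, 3 per group. Across genes, which are not independent replicates, arrays of one group correlated with r from 0.997 to 0.999 and arrays of different groups with r from 0.985 to 0.998. The principal component with the most variance, 51.3%, separated FXRα2 and FXRα4 (scores of 23.4 or more) from GFP, FXRα1 and FXRα3 (−23.0 to −13.7). The next, with 15.1%, separated FXRα2 (16.6 to 19.0) from FXRα4 (−20.6 to −17.0).

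The Nr1h4 probe set reads the mouse gene and therefore checks nothing about the level of the human transgene. The Nr1h4 value was 6.97 ± 0.05 (log2, SD, n = 3) with GFP, 7.01 ± 0.07 with FXRα1, 7.11 ± 0.06 with FXRα2, 6.95 ± 0.05 with FXRα3 and 7.38 ± 0.05 with FXRα4. It rose with FXRα4 alone of the 4 isoforms, by a log2 of 0.41 ± 0.07 (limma adjusted p = 0.000117), or 0.20 with median centring. It did not pass with FXRα1 (adjusted p = 0.812), FXRα2 (adjusted p = 0.175) or FXRα3 (adjusted p = 0.955).

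Of 18820 genes tested with limma against GFP at a Benjamini-Hochberg adjusted p under 0.05, FXRα1 changed 2336, FXRα2 6448, FXRα3 2647 and FXRα4 6352. Changes of at least 2-fold were fewer, at 98, 595, 92 and 570 genes in the same order. Values in parentheses after a gene are log2 fold changes ± SE from limma, with 3 arrays per group, and list calls are said to hold when they also passed with an estimated correlation in place of the preset one. Directions are relative to the deposited scale: when each array was centred on its median, the median change of all genes moved by −0.10 for FXRα1, −0.22 for FXRα2, −0.21 for FXRα4, −0.12 for FXRα2 against FXRα1, −0.17 for FXRα4 against FXRα3 and −0.15 for the insert. Changes smaller than these shifts therefore depend on the scaling, and those named here kept their direction unless stated. With centring on the 75th percentile, centring on the brighter genes and quantile normalization, that median moved by −0.054 to 0.040 over the 9 comparisons.

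**Figure D1:**
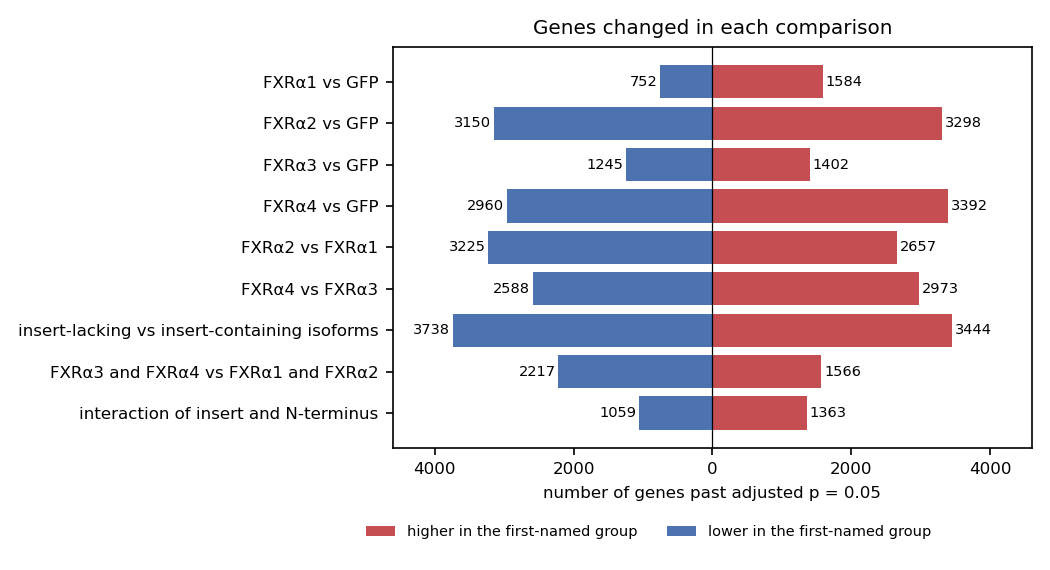
Bars show the number of genes (horizontal axis) higher and lower at an adjusted p under 0.05 in each of the 9 comparisons. FXRα2 and FXRα4 changed 6448 and 6352 genes against GFP, and FXRα1 and FXRα3 changed 2336 and 2647.

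FXRα1 against GFP asked which genes the isoform with the insert and the shorter N-terminus regulates. FXRα1 raised Abcb11, the gene of the bile salt export pump and a known FXR target, together with the ligand genes Bmp7 and Bmp2 and the multidrug transporter gene Abcb1a. It lowered the vasopressin receptor gene Avpr1a and the chemokine gene Ccl20. Among gene groups, 8 hepatobiliary transporter genes rose and 0 fell, 11 genes of the oxidative stress response rose and 1 fell, and 10 genes of the type I interferon response fell and 0 rose. The interferon median was −0.38, and −0.19 without GFP replicate 1, and this list did not hold (adjusted p = 0.368 with an estimated correlation). FXRα1 changed 2336 genes, of which 1584 rose and 752 fell. The share that rose was 67.8%, against 32.7% with median centring, 51.5% with 75th percentile centring, 49.8% with centring on the brighter genes and 53.8% with quantile normalization.

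The largest rises were in Abcb11 (3.01 ± 0.13), Bmp7 (2.92 ± 0.13), Morc4 (2.77 ± 0.06) and Adssl1 (2.37 ± 0.12), the LIM homeobox gene Lhx2 (2.29 ± 0.15), Rflnb (2.23 ± 0.09), Abcb1a (2.14 ± 0.07) and Bmp2 (2.07 ± 0.11), the carbonyl reductase gene Cbr3 (2.01 ± 0.19) and the filamin gene Flnc (1.99 ± 0.08). Abcb11 stood at 5.17 ± 0.12 (SD, n = 3) with GFP and 8.18 ± 0.27 with FXRα1. A dimmer probe set of Bmp7 did not pass with every probe set tested (−0.081, limma adjusted p = 0.667). The largest falls were in Lce6a (−1.97 ± 0.12), a late cornified envelope gene, Avpr1a (−1.44 ± 0.10), Tnfrsf22 (−1.35 ± 0.11), Mboat1 (−1.35 ± 0.11), Ccl20 (−1.20 ± 0.09), Atg10 (−1.10 ± 0.09) and Prnd (−1.06 ± 0.09). Other FXR targets that rose were the phospholipid transporter gene Abcb4 (0.65 ± 0.07), the conjugate export pump gene Abcc2 (0.52 ± 0.04), and Apoc2 (0.54 ± 0.07), whereas Osgin1 (−0.89 ± 0.06) and Fgb (−0.38 ± 0.07) fell. The small heterodimer partner gene Nr0b2, a classical FXR target, did not pass (−0.017 ± 0.13, adjusted p = 0.965), and its sign changed with quantile normalization to 0.001. Cyp8b1, which encodes the 12α-hydroxylase of bile acid synthesis, rose by 0.91 ± 0.11, and Cyp7a1 did not pass here or in any other comparison.

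Of the 26 gene lists, 8 passed camera at a Benjamini-Hochberg adjusted p under 0.05. For hepatobiliary transporters, 8 of 19 genes rose and 0 fell (8 and 3 adjusted over the list alone), with median log2 0.16, camera adjusted p = 0.000809. In the oxidative stress (NRF2) list, 11 of 20 genes rose and 1 fell (12 and 3 adjusted over the list alone), with median log2 0.17, camera adjusted p = 1.16e-06, led by Gsta4 (0.94 ± 0.07) and Gstm4 (0.76 ± 0.06). Of the FXR targets, 8 of 25 genes rose and 2 fell (9 and 2 adjusted over the list alone), with median log2 0.075, and −0.029 with median centring, camera adjusted p = 0.00702, and a median of 0.15 without FXRα1 replicate 2. These 3 held at adjusted p = 0.0488 with an estimated correlation, and the other 5 did not (adjusted p = 0.218 to 0.43 with an estimated correlation). The 3 that held share members and are not independent: Abcb11, Abcb4 and Abcc2 are in both the transporter and the FXR target lists, and Abcc2 is in the NRF2 list too. In the interferon list, 0 of 25 genes rose and 10 fell (0 and 13 adjusted over the list alone), led by Gbp2 (−0.97 ± 0.15) and Ifih1 (−0.41 ± 0.09), with median log2 −0.38, camera adjusted p = 1.86e-06. GFP replicate 1 had high interferon genes, and without it the median was −0.19 (camera adjusted p = 0.00207). In amino acid catabolism and the urea cycle, 10 of 36 genes rose and 2 fell (11 and 2 adjusted over the list alone), with median log2 0.12, camera adjusted p = 0.00107, and a median of 0.22 without FXRα1 replicate 2; the homogentisate dioxygenase gene Hgd (1.08 ± 0.13) rose and the tyrosine aminotransferase gene Tat (−0.65 ± 0.07) fell. In glucose metabolism, 6 of 21 genes rose and 2 fell (12 and 3 adjusted over the list alone), with median log2 0.16, camera adjusted p = 0.00901, and a median of 0.0905 without FXRα1 replicate 3; the glucokinase regulator gene Gckr (0.90 ± 0.09) rose and the pyruvate kinase gene Pklr (−0.72 ± 0.06) fell. For cholesterol synthesis and uptake, 0 of 20 genes rose and 5 fell (0 and 6 adjusted over the list alone), among them Fdps (−0.38 ± 0.05) and Fdft1 (−0.34 ± 0.07), with median log2 −0.11, camera adjusted p = 0.00238, and a median of −0.0725 without FXRα1 replicate 2. Apolipoproteins and lipoprotein metabolism passed with median log2 0.073, and −0.031 with median centring, camera adjusted p = 0.014, and lost the call without GFP replicate 3 (0.083) and without the dimmest genes (0.057).

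FXRα2 against GFP asked the same of the isoform without the insert and with the shorter N-terminus, the form named in the study's title beside lipolysis and fatty acid metabolism. FXRα2 raised the lipid droplet gene Cidec, the epithelial adhesion gene Epcam, the brain creatine kinase gene Ckb and the T-box gene Eomes, and lowered the iodide transporter gene Slc5a5 and the keratin gene Krt19. Of the lipolysis and lipid droplet genes 14 rose and 3 fell, of the apolipoprotein genes 20 rose and 2 fell, and of the amino acid catabolism genes 26 rose and 2 fell. The acute phase list had 15 genes higher and 1 lower, and the FXR target list 16 higher and 4 lower. Of these lists, amino acid catabolism did not hold. FXRα2 changed 6448 genes, 3298 upwards and 3150 downwards. So 51.1% rose, against 14.4% with median centring and 43.0% to 49.7% with the remaining scalings.

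The largest rises were in Ckb (5.15 ± 0.20), Epcam (4.95 ± 0.10), Eomes (4.61 ± 0.14) and Sgk2 (4.21 ± 0.10), the zinc finger gene Zic2 (4.09 ± 0.13), the neprilysin gene Mme (3.92 ± 0.11), Efhd1 (3.74 ± 0.17), Cidec (3.73 ± 0.10) and Il17d (3.64 ± 0.12) and the calcium channel gene Cacna1b (3.62 ± 0.12). Cidec stood at 6.04 ± 0.13 (SD, n = 3) with GFP and 9.77 ± 0.14 with FXRα2. The falls were smaller, with Slc5a5 (−2.59 ± 0.11), Lce6a (−2.27 ± 0.12), Tinagl1 (−1.89 ± 0.06), Mboat1 (−1.84 ± 0.11) and Krt19 (−1.82 ± 0.09), the intermediate filament gene Nes (−1.77 ± 0.11), Avpr1a (−1.72 ± 0.10) and Rab11fip5 (−1.71 ± 0.09) among the largest. Rbl1 was among them at −1.718, but its dimmer probe set rose by 0.377 (limma adjusted p = 0.024 with every probe set tested). Among FXR targets, Abcb11 (3.36 ± 0.13) and Pdk4 (2.18 ± 0.12), the fibrinogen chain genes Fga (1.06 ± 0.08), Fgg (0.77 ± 0.10) and Fgb (0.67 ± 0.07), Apoc2 (0.93 ± 0.07) and Abcb4 (0.86 ± 0.07) and the fatty acid receptor gene Ppara (0.71 ± 0.09) rose. Osgin1 (−0.90 ± 0.06) and Abcc2 (−0.39 ± 0.04) fell, Abcc2 standing at −0.61 with median centring. Nr0b2 passed at 0.40 ± 0.13, and at 0.26 with 16 added to the linear values, but not with median centring (0.18) or centring on the brighter genes (0.36), and the call was lost without FXRα2 replicate 2 (0.26, adjusted p = 0.132), GFP replicate 2 (0.37, adjusted p = 0.0555) or GFP replicate 3 (0.38, adjusted p = 0.0524). Cyp8b1 rose by 1.65 ± 0.11.

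Camera passed 13 of the 26 lists, all of them upwards, and 5 held at adjusted p = 0.00875 to 0.0314 with an estimated correlation. For lipolysis and lipid droplets, 14 of 25 genes rose and 3 fell (the same adjusted over the list alone), with median log2 0.22, and −0.0026 with median centring, camera adjusted p = 8.97e-05. Beside Cidec, that list was led by Cidea (1.70 ± 0.10) and Cideb (0.94 ± 0.06) and the lipase coactivator gene Abhd5 (0.92 ± 0.05). Among apolipoproteins and lipoprotein metabolism genes, 20 of 26 genes rose and 2 fell (21 and 2 adjusted over the list alone), with median log2 0.35, camera adjusted p = 2.46e-07, led by the endothelial lipase gene Lipg (2.48 ± 0.15), Apom (1.04 ± 0.07) and Lcat (0.94 ± 0.08). Among FXR targets, 16 of 25 genes rose and 4 fell (17 and 4 adjusted over the list alone), with median log2 0.38, camera adjusted p = 4.51e-05. In the acute phase list, 15 of 22 genes rose and 1 fell (the same adjusted over the list alone), with median log2 0.33, camera adjusted p = 8.2e-07, including the orosomucoid genes Orm3 (3.25 ± 0.11) and Orm2 (2.11 ± 0.07) and the cytokine feedback gene Socs3 (1.36 ± 0.11). A dimmer probe set of Socs3 did not pass with every probe set tested (0.353, limma adjusted p = 0.0958). In hepatocyte identity, 9 of 20 genes rose and 0 fell (10 and 0 adjusted over the list alone), with median log2 0.24, camera adjusted p = 5e-05, among them the transcription factor genes Hnf4a (1.54 ± 0.05), Foxa1 (1.49 ± 0.07), Prox1 (0.99 ± 0.10) and Cebpa (0.79 ± 0.07).

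The other 8 lists did not hold (adjusted p = 0.0552 to 0.487 with an estimated correlation). In amino acid catabolism and the urea cycle, 26 of 36 genes rose and 2 fell (27 and 2 adjusted over the list alone), with median log2 0.37, camera adjusted p = 5.98e-10, including Hgd (3.12 ± 0.13), Uroc1 (2.48 ± 0.14) and Nags (1.12 ± 0.07), while Tat (−1.28 ± 0.07) fell. For complement and coagulation, 17 of 33 genes rose and 2 fell (17 and 3 adjusted over the list alone), with median log2 0.21, and −0.015 with median centring, camera adjusted p = 3.81e-05. For hepatobiliary transporters, 8 of 19 genes rose and 3 fell (the same adjusted over the list alone), with median log2 0.18, and −0.043 with median centring, camera adjusted p = 0.00822, and a median of 0.11 without GFP replicate 1. Abcb1a (3.04 ± 0.07) rose and Abcc4 (−0.99 ± 0.07) fell. In ketogenesis, 5 of 7 genes rose and 1 fell (the same adjusted over the list alone), with median log2 0.45, camera adjusted p = 0.00757, led by the ketone body dehydrogenase gene Bdh1 (1.42 ± 0.11). In the cell cycle list, 12 of 24 genes rose and 2 fell (16 and 2 adjusted over the list alone), with median log2 0.37, camera adjusted p = 9.05e-05, and a median of 0.21 without FXRα2 replicate 3. Cdc20 (2.18 ± 0.20), Rrm2 (1.67 ± 0.14) and Plk1 (1.64 ± 0.14) rose. For fatty acid oxidation, 13 of 30 genes rose and 5 fell (13 and 6 adjusted over the list alone), with median log2 0.16, and −0.066 with median centring, camera adjusted p = 0.0302. Decr2 (0.88 ± 0.06) and Eci2 (0.68 ± 0.06) rose and the carnitine acetyltransferase gene Crat (−0.81 ± 0.06) fell. That call was lost with median centring (camera adjusted p = 0.223), with quantile normalization (0.0558), without the dimmest genes (0.106), without FXRα2 replicate 1 (0.0526) and without GFP replicate 3 (0.0654). Cholesterol synthesis and uptake passed with median log2 0.19, and −0.028 with median centring, camera adjusted p = 0.0347, and lost the call with median centring (0.174), with quantile normalization (0.0798), without the dimmest genes (0.109) and without FXRα2 replicate 1 (0.0545), FXRα2 replicate 2 (0.0634) or GFP replicate 3 (0.0654). Glucose metabolism passed with median log2 0.13, and −0.095 with median centring, camera adjusted p = 0.0131, with a median of 0.0763 without FXRα2 replicate 1 and 0.20 without FXRα2 replicate 2, and lost the call without the dimmest genes (0.064).

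**Figure D2:**
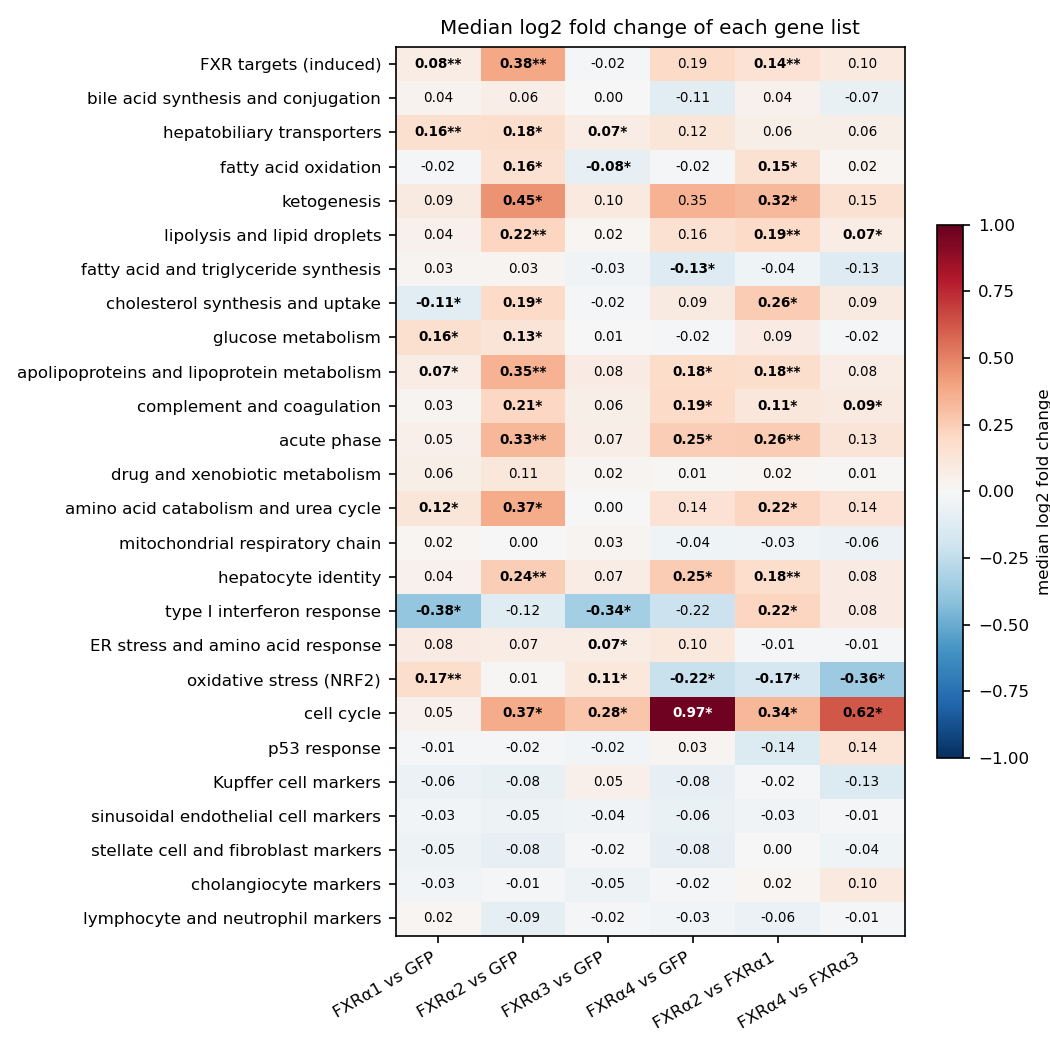
Cells give the median log2 fold change of each of the 26 gene lists (vertical axis) in 6 comparisons (horizontal axis); 1 star marks a camera adjusted p under 0.05 and 2 stars mark lists that also passed with an estimated correlation. Lipolysis and lipid droplets had a median of 0.22 with FXRα2 (−0.0026 with median centring), and cell cycle had a median of 0.97 with FXRα4.

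FXRα3 against GFP asked the same of the isoform with the insert and the longer N-terminus. FXRα3 raised the chemokine gene Cxcl2, the phosphatase gene Dusp4, Krt19 and Abcb1a, and lowered the oxidative stress target Osgin1, the retinol dehydrogenase gene Dhrs9 and Avpr1a. Of the fatty acid oxidation genes 8 fell and 0 rose, and of the interferon genes 9 fell and 0 rose (median log2 −0.34, and −0.16 without GFP replicate 1). Neither list held (adjusted p = 0.527 for both with an estimated correlation). Of the oxidative stress genes 9 rose and 2 fell, and of the cell cycle genes 9 rose and 1 fell, and these lists did not hold either. FXRα3 changed 2647 genes, 1402 upwards and 1245 downwards, against 1220 and 1838 with median centring.

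The largest rises were in Morc4 (2.86 ± 0.06), Lce1d (2.63 ± 0.12), Lhx2 (2.24 ± 0.15), Cxcl2 (2.22 ± 0.09), Dusp4 (2.12 ± 0.09), Abcb1a (1.87 ± 0.07) and Rpp25 (1.82 ± 0.13), the zinc transporter gene Slc30a3 (1.82 ± 0.10), Krt19 (1.76 ± 0.09) and Cbr3 (1.72 ± 0.19). The largest falls were in Lce6a (−2.17 ± 0.12), Avpr1a (−1.93 ± 0.10), Osgin1 (−1.87 ± 0.06) and Dhrs9 (−1.71 ± 0.10), the urate pathway gene Urad (−1.36 ± 0.10), Cnn1 (−1.36 ± 0.11) and Atg10 (−1.35 ± 0.09). Of the FXR targets, Pdk4 (0.83 ± 0.12), Apoc2 (0.60 ± 0.07) and Abcc2 (0.34 ± 0.04) and the bile acid ligase gene Slc27a5 (0.34 ± 0.06) rose. Insig2 (−0.38 ± 0.04) fell. Abcb11 passed at 0.49 ± 0.13, but not without FXRα3 replicate 3 (0.35, adjusted p = 0.0869) or GFP replicate 2 (0.43, adjusted p = 0.0582). Nr0b2 passed at −0.46 ± 0.13, and at −0.26 with 16 added, but not without FXRα3 replicate 3 (−0.43, adjusted p = 0.0595) or GFP replicate 1 (−0.41, adjusted p = 0.0699). Cyp8b1 rose by 0.65 ± 0.11. The FXR target list as a group did not pass (camera adjusted p = 0.637).

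Camera passed 6 lists, and none of the 6 held (adjusted p = 0.276 to 0.527 with an estimated correlation). Among cell cycle genes, 9 of 24 genes rose and 1 fell (12 and 1 adjusted over the list alone), with median log2 0.28, camera adjusted p = 1.06e-05, and a median of 0.18 without FXRα3 replicate 3. Rrm2 (0.75 ± 0.14) and Cdk1 (0.56 ± 0.08) rose. In the NRF2 list, 9 of 20 genes rose and 2 fell (10 and 2 adjusted over the list alone), with median log2 0.11, camera adjusted p = 0.000435, and the quinone oxidoreductase gene Nqo1 (1.41 ± 0.07) and the cystine transporter gene Slc7a11 (0.62 ± 0.04) rose. In the interferon list, 0 of 25 genes rose and 9 fell (1 and 14 adjusted over the list alone), with median log2 −0.34, camera adjusted p = 0.000435, among them Gbp2 (−0.93 ± 0.15) and Ifih1 (−0.51 ± 0.09). Without GFP replicate 1 the interferon median was −0.16 (camera adjusted p = 0.0175). For fatty acid oxidation, 0 of 30 genes rose and 8 fell (1 and 10 adjusted over the list alone), with median log2 −0.081, camera adjusted p = 0.000566, and the falls included Acot4 (−0.81 ± 0.10), Acad11 (−0.64 ± 0.05), Crat (−0.51 ± 0.06) and Etfdh (−0.39 ± 0.06). Hepatobiliary transporters passed with median log2 0.073, camera adjusted p = 0.031, and a median of 0.042 without FXRα3 replicate 1, and lost the call without GFP replicate 3 (0.052), without the dimmest genes (0.0653) and with quantile normalization (0.0527). ER stress and the amino acid response passed with median log2 0.072, camera adjusted p = 0.0238, and lost the call with median centring (0.0597), without the dimmest genes (0.0635) and with quantile normalization (0.0527).

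FXRα4 against GFP asked the same of the isoform without the insert and with the longer N-terminus. FXRα4 raised Epcam, Cidec and the division genes Cep55 and Nek2, and lowered Slc5a5, Osgin1 and the Wnt coreceptor gene Lrp5. Of the 24 measured cell cycle genes 19 rose and 0 fell. Of the oxidative stress genes 12 fell and 3 rose, and of the fatty acid and triglyceride synthesis genes 11 fell and 4 rose. The acute phase list had 12 genes higher and 2 lower. None of these list calls held. FXRα4 changed 6352 genes, 3392 upwards and 2960 downwards. So 53.4% rose, against 16.3% with median centring and 48.0% to 56.1% with the remaining scalings.

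The largest rises were in Epcam (4.68 ± 0.10), Ttc9 (3.54 ± 0.12), Cidec (3.31 ± 0.10), Cep55 (3.25 ± 0.17) and Eomes (3.24 ± 0.14), the costimulatory ligand gene Cd80 (3.20 ± 0.18), Flicr (3.20 ± 0.14), Il17d (3.14 ± 0.12), Lrrc2 (3.13 ± 0.13) and Nek2 (3.12 ± 0.12). A dimmer probe set of Cd80 rose by 1.625. The largest falls included Slc5a5 (−2.95 ± 0.11), Lce6a (−2.32 ± 0.12), Nexmif (−1.99 ± 0.15), Avpr1a (−1.84 ± 0.10), Mboat1 (−1.77 ± 0.11), Osgin1 (−1.66 ± 0.06), Lrp5 (−1.59 ± 0.07), Shroom1 (−1.53 ± 0.08) and Dhrs9 (−1.52 ± 0.10). Rbl1 was among them at −2.016, but its dimmer probe set rose by 0.431 (limma adjusted p = 0.0102 with every probe set tested). Among FXR targets, Abcb11 (1.87 ± 0.13), Pdk4 (1.17 ± 0.12) and Apoc2 (0.87 ± 0.07) and the lipoprotein receptor gene Vldlr (0.75 ± 0.07) rose. Osgin1 (−1.66 ± 0.06), Mafg (−0.68 ± 0.07) and Abcc2 (−0.35 ± 0.04) fell, Abcc2 standing at −0.56 with median centring. In all, 12 of 25 genes rose and 7 fell (13 and 7 adjusted over the list alone) in this list, which did not pass as a group (camera adjusted p = 0.194). Nr0b2 passed at −0.39 ± 0.13, at −0.60 with median centring and at −0.22 with 16 added, and the call was lost without FXRα4 replicate 2 (−0.35, adjusted p = 0.0698), FXRα4 replicate 3 (−0.33, adjusted p = 0.0861) or GFP replicate 1 (−0.34, adjusted p = 0.0812).

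Camera passed 7 lists, and none of the 7 held (adjusted p = 0.24 to 0.488 with an estimated correlation). In the cell cycle list, 19 of 24 genes rose and 0 fell (the same adjusted over the list alone), with median log2 0.97, camera adjusted p = 2.96e-14. Cdc20 (2.90 ± 0.20), Rrm2 (2.87 ± 0.14), Aurka (1.98 ± 0.12) and Plk1 (1.97 ± 0.14) rose. The mean of this list in each array, relative to the mean of all 15, was 0.80 ± 0.18 (SD, n = 3) with FXRα4 and −0.41 ± 0.06 with GFP, and all 3 FXRα4 arrays lay above all 3 GFP arrays. In the NRF2 list, 3 of 20 genes rose and 12 fell (the same adjusted over the list alone), with median log2 −0.22, camera adjusted p = 0.00321. Gsta4 (−0.89 ± 0.07) and Gclm (−0.68 ± 0.05) fell and Nqo1 (1.43 ± 0.07) rose. For fatty acid and triglyceride synthesis, 4 of 25 genes rose and 11 fell (4 and 12 adjusted over the list alone), with median log2 −0.13, camera adjusted p = 0.00877, and the acyltransferase gene Gpam (−0.85 ± 0.05), the elongase gene Elovl5 (−0.79 ± 0.05) and the lipin gene Lpin1 (−0.71 ± 0.07) fell. In the acute phase list, 12 of 22 genes rose and 2 fell (13 and 2 adjusted over the list alone), with median log2 0.25, camera adjusted p = 0.00706. Orm3 (2.06 ± 0.11) and Orm2 (0.98 ± 0.07) rose and Apcs (−0.67 ± 0.06) fell. In hepatocyte identity, 10 of 20 genes rose and 2 fell (the same adjusted over the list alone), with median log2 0.25, camera adjusted p = 0.00877. Prox1 (1.03 ± 0.10) and Hnf4a (0.86 ± 0.05) rose. For apolipoproteins and lipoprotein metabolism, 13 of 26 genes rose and 4 fell (the same adjusted over the list alone), with median log2 0.18, and −0.031 with median centring, camera adjusted p = 0.0035. For complement and coagulation, 17 of 33 genes rose and 3 fell (the same adjusted over the list alone), with median log2 0.19, and −0.024 with median centring, camera adjusted p = 0.00413.

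**Figure D3:**
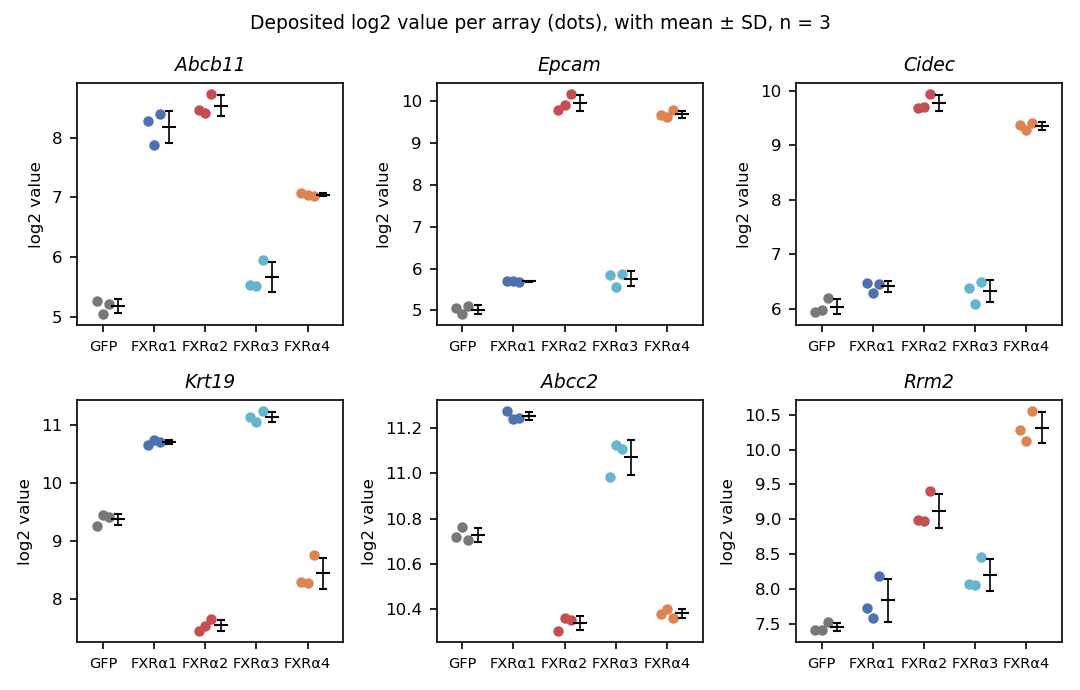
Points give the log2 level (vertical axis) of Abcb11, Epcam, Cidec, Krt19, Abcc2 and Rrm2 in each array of the 5 groups (horizontal axis), with bars at the mean ± SD of 3 arrays. Abcb11 was at 5.17 with GFP and 8.18 with FXRα1, and the Rrm2 rise over GFP was 2.87 with FXRα4 and 1.67 with FXRα2.

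The 4 comparisons with GFP shared the same 3 control arrays, which on its own makes their changes correlate: for simulated unchanged groups the expected r across genes was 0.501 and the covariance 0.0045. FXRα2 and FXRα4 together raised 2229 genes, against 594 expected for independent calls, and lowered 1948, against 495. They changed 193 of the 4370 genes called in both in opposite directions (4.42%). Their changes correlated with r = 0.773, and the covariance of 0.122 exceeded the simulated one by 0.117. FXRα1 and FXRα3 together raised 874 genes, against 118 expected, and lowered 510, against 49.7, with 31 of 1415 opposite (2.19%), r = 0.707 and a covariance of 0.0317, or 0.0272 above the simulated 0.0045. In the pairs that share the N-terminus, FXRα1 and FXRα2 changed 1509 genes the same way and 199 of 1708 opposite (11.7%), with r = 0.491 and a covariance 0.0374 above the simulated one. FXRα3 and FXRα4 changed 1737 the same way and 205 of 1942 opposite (10.6%), with r = 0.516 and a covariance 0.0382 above. In the pairs that share neither feature, FXRα1 and FXRα4 changed 1358 the same way and 262 of 1620 opposite (16.2%), and FXRα2 and FXRα3 1589 and 284 of 1873 (15.2%). Their r was 0.419 and 0.429, and their covariances were 0.0302 and 0.0321 above the simulated ones. All 4 isoforms raised 536 genes and lowered 315, and 87 more were called in all 4 with mixed directions. The 3 control arrays cannot be divided into parts of at least 2, so part of the excess may come from the shared controls.

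FXRα2 against FXRα1 compared the isoforms with the shorter N-terminus, without and with the insert, and used no GFP array in the contrast. Ckb, Epcam, Cidec and Orm3 were higher with FXRα2, and Krt19, Cbr3 and the semaphorin gene Sema3e were lower. Of the lipolysis and lipid droplet genes 12 were higher and 2 lower, of the cholesterol synthesis genes 12 were higher and 1 lower, and of the acute phase genes 13 were higher and 0 lower. Of the oxidative stress genes 10 were lower and 2 higher. The cholesterol synthesis and oxidative stress lists did not hold. In all, 5882 genes differed, 2657 upwards and 3225 downwards, so 45.2% were higher, against 22.8% with median centring.

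The largest differences upwards were in Ckb (5.05 ± 0.20), Epcam (4.27 ± 0.10), Efhd1 (3.65 ± 0.17), Zic2 (3.59 ± 0.13), Cacna1b (3.57 ± 0.12), Cidec (3.36 ± 0.10), Lrrc2 (3.34 ± 0.13), Eomes (3.16 ± 0.14), Orm3 (3.04 ± 0.11) and Il17d (2.93 ± 0.12). The largest downwards included Krt19 (−3.15 ± 0.09), Cbr3 (−2.40 ± 0.19), Sema3e (−2.39 ± 0.10), Nes (−1.91 ± 0.11), Slc5a5 (−1.91 ± 0.11), Serpinb9e (−1.90 ± 0.12), Fam171b (−1.83 ± 0.08) and Tinagl1 (−1.46 ± 0.06). Rbl1 was among them at −1.704, but its dimmer probe set did not pass (0.258, limma adjusted p = 0.139 with every probe set tested). Among FXR targets, Fga (1.18 ± 0.08), Fgb (1.05 ± 0.07), Pdk4 (0.99 ± 0.12) and Ppara (0.58 ± 0.09) were higher and Abcc2 (−0.91 ± 0.04) lower. Cyp8b1 was higher by 0.74 ± 0.11.

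Camera passed 13 lists, 12 upwards, and 5 held at adjusted p = 0.0213 to 0.0373 with an estimated correlation. For the FXR targets, 13 of 25 genes were higher and 3 lower (13 and 4 adjusted over the list alone) in FXRα2 relative to FXRα1, with median log2 0.14, camera adjusted p = 0.000885. For lipolysis and lipid droplets, 12 of 25 genes were higher and 2 lower (12 and 3 adjusted over the list alone), with median log2 0.19, camera adjusted p = 2.92e-05. Cidea (1.45 ± 0.10), Plin3 (0.80 ± 0.06) and Abhd5 (0.68 ± 0.05) were higher. For apolipoproteins and lipoprotein metabolism, 16 of 26 genes were higher and 3 lower (the same adjusted over the list alone), with median log2 0.18, camera adjusted p = 3.1e-05, and Lipg (2.43 ± 0.15), the lipase inhibitor gene Angptl8 (1.05 ± 0.09) and the sortilin gene Sort1 (0.96 ± 0.08) were higher. In the acute phase list, 13 of 22 genes were higher and 0 lower (the same adjusted over the list alone), with median log2 0.26, camera adjusted p = 2.29e-07, led by Orm3 (3.04 ± 0.11), Orm2 (2.25 ± 0.07) and Il1rn (1.25 ± 0.11). In hepatocyte identity, 9 of 20 genes were higher and 1 lower (the same adjusted over the list alone), with median log2 0.18, camera adjusted p = 7.73e-05, including Foxa1 (0.91 ± 0.07) and Cebpa (0.85 ± 0.07).

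The remaining 8 lists did not hold (adjusted p = 0.0579 to 0.454 with an estimated correlation). For cholesterol synthesis and uptake, 12 of 20 genes were higher and 1 lower (13 and 1 adjusted over the list alone), with median log2 0.26, camera adjusted p = 2.92e-05. Hmgcs1 (0.69 ± 0.05) and Msmo1 (0.64 ± 0.06) were higher and Lss (−0.56 ± 0.06) was lower. For amino acid catabolism and the urea cycle, 17 of 36 genes were higher and 3 lower (18 and 3 adjusted over the list alone), with median log2 0.22, camera adjusted p = 3.69e-07. Uroc1 (2.44 ± 0.14) and Hgd (2.04 ± 0.13) were higher. For fatty acid oxidation, 12 of 30 genes were higher and 6 lower (14 and 7 adjusted over the list alone), with median log2 0.15, camera adjusted p = 0.00265. Decr2 (0.92 ± 0.06) was higher. In the NRF2 list, 2 of 20 genes were higher and 10 lower (2 and 11 adjusted over the list alone), with median log2 −0.17, camera adjusted p = 0.000519. Slc7a11 (−0.85 ± 0.04) and Srxn1 (−0.72 ± 0.06) were lower. Among cell cycle genes, 14 of 24 genes were higher and 2 lower (the same adjusted over the list alone), with median log2 0.34, camera adjusted p = 9.15e-05. Cdc20 (2.05 ± 0.20) and Plk1 (1.70 ± 0.14) were higher. Complement and coagulation passed with median log2 0.11, and −0.0032 with median centring, camera adjusted p = 3.1e-05. The interferon list passed with median log2 0.22, camera adjusted p = 0.00138, and a median of 0.0902 without FXRα2 replicate 1 and 0.33 without FXRα2 replicate 2. Ketogenesis passed with median log2 0.32, camera adjusted p = 0.023, and lost the call without FXRα2 replicate 1 (0.0521), without the dimmest genes (0.0632) and with quantile normalization (0.0564).

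FXRα4 against FXRα3 made the same comparison among the isoforms with the longer N-terminus. Epcam, Cidec, the ephrin gene Efnb2 and the division genes Cep55 and Kif18b were higher with FXRα4, and Krt19, Cbr3 and the pyrimidine synthesis gene Umps were lower. Of the 24 measured cell cycle genes 20 were higher and 1 lower, and of the 20 oxidative stress genes 14 were lower and 1 higher. Neither list call held. In all, 5561 genes differed, 2973 upwards and 2588 downwards, so 53.5% were higher, against 18.4% with median centring.

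The largest differences upwards were in Epcam (3.94 ± 0.10), Cep55 (3.37 ± 0.17), Ttc9 (3.20 ± 0.12), Cidec (3.02 ± 0.10), Efnb2 (2.99 ± 0.14), Cd80 (2.90 ± 0.18) and Lrrc2 (2.85 ± 0.13), the phosphate transporter gene Slc17a1 (2.78 ± 0.10), and Kif18b (2.74 ± 0.13). With every probe set tested, a dimmer one of Kif18b did not pass (0.187, limma adjusted p = 0.145) and a dimmer one of Cd80 stood at 1.629. The largest downwards included Krt19 (−2.69 ± 0.09), Cbr3 (−2.29 ± 0.19), Slc5a5 (−1.93 ± 0.11), Sema3e (−1.84 ± 0.10), Serpinb9e (−1.71 ± 0.12), Umps (−1.66 ± 0.05), Pcolce2 (−1.65 ± 0.11), Lce1d (−1.55 ± 0.12) and Plek2 (−1.54 ± 0.11). Rbl1 was among them at −1.986, but its dimmer probe set did not pass (0.294, limma adjusted p = 0.0908 with every probe set tested). Of the FXR targets, Abcb11 (1.38 ± 0.13), Fgb (0.63 ± 0.07), Fga (0.60 ± 0.08) and Vldlr (0.54 ± 0.07) were higher. Abcc2 (−0.69 ± 0.04) and Mafg (−0.50 ± 0.07) were lower. Cyp8b1 was lower (−0.58 ± 0.11).

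Camera passed 4 lists, and none of the 4 held (adjusted p = 0.0802 to 0.544 with an estimated correlation). In the cell cycle list, 20 of 24 genes were higher and 1 lower (20 and 2 adjusted over the list alone) with FXRα4 relative to FXRα3, with median log2 0.62, camera adjusted p = 1.83e-09, led by Cdc20 (2.44 ± 0.20), Rrm2 (2.13 ± 0.14), Plk1 (2.00 ± 0.14) and Aurka (1.80 ± 0.12). In the NRF2 list, 1 of 20 genes was higher and 14 lower (the same adjusted over the list alone), with median log2 −0.36, camera adjusted p = 1.11e-07. Gsta4 (−1.44 ± 0.07), Gclm (−0.81 ± 0.05) and Slc7a11 (−0.61 ± 0.04) were lower. For complement and coagulation, 11 of 33 genes were higher and 0 lower (the same adjusted over the list alone), with median log2 0.091, and −0.083 with median centring, camera adjusted p = 0.0176, and the call was lost with median centring (0.107) and without the dimmest genes (0.0975). For lipolysis and lipid droplets, 8 of 25 genes were higher and 3 lower (the same adjusted over the list alone), with median log2 0.073, and −0.10 with median centring, camera adjusted p = 0.0356, and the triglyceride lipase gene Pnpla2 (0.76 ± 0.07) and Abhd5 (0.52 ± 0.05) were higher. This call was lost without FXRα4 replicate 2 (camera adjusted p = 0.0533), without the dimmest genes (0.123), with quantile normalization (0.12), with 75th percentile centring (0.0667) and with centring on the brighter genes (0.0566).

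The insert contrast set the mean of FXRα2 and FXRα4 against the mean of FXRα1 and FXRα3, and so asked which differences go with the missing insert on average. Epcam, Ckb, Cidec and Zic2 were higher without the insert, and Krt19, Cbr3, Sema3e and Slc5a5 were lower. Of the cholesterol synthesis genes 13 were higher and 2 lower, of the lipolysis and lipid droplet genes 13 were higher and 3 lower, and of the oxidative stress genes 13 were lower and 2 higher. The cholesterol synthesis list did not hold. In all, 7182 genes differed, 3444 upwards and 3738 downwards, so 48.0% were higher, against 16.6% with median centring. Between the separate pairs, 3469 genes were called in both, 1641 higher in both (420 expected for independent calls), 1618 lower in both (443 expected) and 210 in opposite directions, with r = 0.698 across genes.

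The largest average differences upwards were in Epcam (4.10 ± 0.07), Ckb (3.69 ± 0.14), Cidec (3.19 ± 0.07), Lrrc2 (3.09 ± 0.09), Zic2 (3.03 ± 0.09), Efnb2 (2.87 ± 0.10), Ttc9 (2.86 ± 0.08), Cacna1b (2.83 ± 0.09) and Il17d (2.65 ± 0.08) and the mitochondrial carrier gene Slc25a35 (2.60 ± 0.09). The largest downwards included Krt19 (−2.92 ± 0.06), Cbr3 (−2.35 ± 0.14), Sema3e (−2.11 ± 0.07), Slc5a5 (−1.92 ± 0.08), Serpinb9e (−1.80 ± 0.08), Fam171b (−1.66 ± 0.06), Umps (−1.45 ± 0.04) and Cdr2l (−1.34 ± 0.09). Rbl1 was among them at −1.845, but its dimmer probe set was higher by 0.276 (limma adjusted p = 0.0176 with every probe set tested). Among FXR targets, Fga (0.89 ± 0.06), Abcb11 (0.87 ± 0.09), Fgb (0.84 ± 0.05) and Pdk4 (0.67 ± 0.08) were higher and Abcc2 (−0.80 ± 0.03) was lower. Abcc2 rose against GFP with FXRα1 and FXRα3 and fell with FXRα2 and FXRα4.

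Camera passed 11 lists, and 5 held at adjusted p = 0.0428 with an estimated correlation. For the FXR targets, 14 of 25 genes were higher and 3 lower (15 and 3 adjusted over the list alone) without the insert, with median log2 0.12, and −0.027 with median centring, camera adjusted p = 0.00212. In lipolysis and lipid droplets, 13 of 25 genes were higher and 3 lower (13 and 4 adjusted over the list alone), with median log2 0.14, and −0.00067 with median centring, camera adjusted p = 0.000281. Pnpla2 (0.84 ± 0.05), Abhd5 (0.60 ± 0.03) and Plin3 (0.59 ± 0.04) were higher. For apolipoproteins, 14 of 26 genes were higher and 3 lower (15 and 3 adjusted over the list alone), with median log2 0.14, and −0.0091 with median centring, camera adjusted p = 0.000281. Lipg (2.19 ± 0.11) and Sort1 (1.19 ± 0.06) were higher and Angptl4 (−0.57 ± 0.05) was lower. In the acute phase list, 12 of 22 genes were higher and 1 lower (the same adjusted over the list alone), with median log2 0.19, camera adjusted p = 6.1e-05, including Orm3 (2.32 ± 0.08) and Orm2 (1.55 ± 0.05). In the NRF2 list, 2 of 20 genes were higher and 13 lower (3 and 13 adjusted over the list alone), with median log2 −0.27, camera adjusted p = 1.37e-05. Gsta4 (−0.84 ± 0.05), Slc7a11 (−0.73 ± 0.03) and Srxn1 (−0.68 ± 0.04) were lower. The other 6 did not hold (adjusted p = 0.0878 to 0.606 with an estimated correlation). Among cell cycle genes, 19 of 24 genes were higher and 2 lower (the same adjusted over the list alone), with median log2 0.42, camera adjusted p = 1.05e-07. Cdc20 (2.25 ± 0.14), Plk1 (1.85 ± 0.10) and Rrm2 (1.71 ± 0.10) were higher. For cholesterol synthesis and uptake, 13 of 20 genes were higher and 2 lower (the same adjusted over the list alone), with median log2 0.17, camera adjusted p = 0.000293, including Hmgcs1 (0.54 ± 0.04) and Srebf2 (0.45 ± 0.04). For amino acid catabolism and the urea cycle, 17 of 36 genes were higher and 4 lower (18 and 4 adjusted over the list alone), with median log2 0.19, camera adjusted p = 7.21e-05. Complement and coagulation passed with median log2 0.10, and −0.044 with median centring, camera adjusted p = 0.000122, and hepatocyte identity with median log2 0.12, and −0.020 with median centring, camera adjusted p = 0.00142. The interferon list passed with median log2 0.11, and −0.036 with median centring, camera adjusted p = 0.0164, with a median of 0.19 without FXRα4 replicate 2, and lost the call without FXRα2 replicate 1 (0.0604), without the dimmest genes (0.0655) and with quantile normalization (0.0515).

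The N-terminus contrast set the mean of FXRα3 and FXRα4 against the mean of FXRα1 and FXRα2. Abcb11, the urate oxidase gene Uox, the pregnane X receptor gene Nr1i2 and Nr0b2 were lower with the longer N-terminus, and the elongase gene Elovl4 and the kinase substrate gene Marcks were higher. Of the FXR targets 12 were lower and 2 higher, of the amino acid catabolism genes 23 were lower and 1 higher, and of the fatty acid oxidation genes 14 were lower and 0 higher. For the lower FXR targets, a difference in receptor dose and one in activity cannot be told apart. The arrays give no separate readout of the human transgene. Of the cell cycle genes 18 were higher and 0 lower. Among these lists, the FXR targets alone held. In all, 3783 genes differed, 1566 upwards and 2217 downwards. The share that was higher was 41.4%, against 56.6% with median centring, 59.2% with 75th percentile centring, 54.7% with centring on the brighter genes and 52.4% with quantile normalization.

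The largest differences upwards were in Elovl4 (1.32 ± 0.08), Marcks (1.18 ± 0.08), Podxl (1.15 ± 0.07), Fam111a (0.99 ± 0.09) and Nanos1 (0.96 ± 0.08), and the largest downwards in Abcb11 (−2.00 ± 0.09), Uox (−1.52 ± 0.09) and Urad (−1.50 ± 0.07), the decarboxylase gene Ddc (−1.44 ± 0.10) and Nr1i2 (−1.44 ± 0.08). Among FXR targets, Osgin1 (−0.87 ± 0.04), Pdk4 (−0.69 ± 0.08), Ppara (−0.52 ± 0.06) and Abcb4 (−0.48 ± 0.05) were also lower. Nr0b2 was lower (−0.61 ± 0.09), and stood at −0.37 with 16 added to the linear values. Cyp8b1 was lower (−0.93 ± 0.08).

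Camera passed 14 lists, 13 downwards and 1 upwards, and the FXR targets alone held (adjusted p = 0.00482 with an estimated correlation; the other 13 adjusted p = 0.0613 to 0.491 with an estimated correlation). For the FXR targets, 2 of 25 genes were higher and 12 lower (2 and 13 adjusted over the list alone) with the longer N-terminus, with median log2 −0.11, camera adjusted p = 1.59e-06. For amino acid catabolism and the urea cycle, 1 of 36 genes was higher and 23 lower (1 and 24 adjusted over the list alone), with median log2 −0.23, camera adjusted p = 4.03e-12. Hgd (−1.38 ± 0.09), Gpt (−0.76 ± 0.06) and Cbs (−0.54 ± 0.04) were lower. In fatty acid oxidation, 0 of 30 genes were higher and 14 lower (1 and 16 adjusted over the list alone), with median log2 −0.13, camera adjusted p = 1.32e-07, including the carnitine palmitoyltransferase gene Cpt1a (−0.62 ± 0.03) and Acot4 (−0.68 ± 0.07). For fatty acid and triglyceride synthesis, 0 of 25 genes were higher and 12 lower (the same adjusted over the list alone), with median log2 −0.10, camera adjusted p = 2.26e-06, including Acacb (−0.68 ± 0.09), Thrsp (−0.63 ± 0.08) and Fasn (−0.38 ± 0.03). For lipolysis and lipid droplets, 2 of 25 genes were higher and 12 lower (3 and 14 adjusted over the list alone), with median log2 −0.18, camera adjusted p = 0.000848. In glucose metabolism, 1 of 21 genes was higher and 12 lower (the same adjusted over the list alone), with median log2 −0.15, camera adjusted p = 8.93e-05. Slc37a4 (−0.57 ± 0.08) was lower. In the cell cycle list, 18 of 24 genes were higher and 0 lower (19 and 0 adjusted over the list alone), with median log2 0.42, camera adjusted p = 1.27e-13. Aurkb (1.02 ± 0.11), Cdk1 (0.88 ± 0.06) and Rrm2 (0.78 ± 0.10) were higher.

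For hepatobiliary transporters, 2 of 19 genes were higher and 8 lower (3 and 9 adjusted over the list alone), with median log2 −0.099, camera adjusted p = 0.00256. In bile acid synthesis and conjugation, 1 of 16 genes was higher and 6 lower (the same adjusted over the list alone), with median log2 −0.065, camera adjusted p = 0.0121. Hsd17b4 (−0.52 ± 0.04) was lower. In the NRF2 list, 3 of 20 genes were higher and 9 lower (3 and 10 adjusted over the list alone), with median log2 −0.072, camera adjusted p = 0.000127, including Gsta4 (−0.99 ± 0.05) and Gstm4 (−0.59 ± 0.04). Ketogenesis passed at camera adjusted p = 0.035 and lost the call without FXRα2 replicate 1 (0.0731), FXRα3 replicate 3 (0.0594) or FXRα4 replicate 3 (0.0526). Apolipoproteins passed at camera adjusted p = 0.041 and lost it without FXRα2 replicate 1 (0.0618), FXRα3 replicate 3 (0.0817) or FXRα4 replicate 1 (0.0522). The mitochondrial respiratory chain, with median log2 −0.031, and 0.0066 with median centring, and 0.0094 with 75th percentile centring, and 0.00041 with centring on the brighter genes, passed at camera adjusted p = 0.0228 and lost the call with these centrings (0.101 to 0.136) and without FXRα1 replicate 2 (0.0788), FXRα2 replicate 1 (0.0623) or FXRα3 replicate 3 (0.0682). Acute phase genes passed at camera adjusted p = 0.0477 and lost the call without FXRα1 replicate 2 (0.102), FXRα2 replicate 1 (0.0652), FXRα3 replicate 2 (0.0538), FXRα3 replicate 3 (0.0682), FXRα4 replicate 1 (0.0818) or FXRα4 replicate 2 (0.0545). These 4 calls were also lost without the dimmest genes (0.0844 to 0.125).

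The interaction asked whether the difference between isoforms without and with the insert depends on the N-terminus, as the FXRα4 minus FXRα3 difference less the FXRα2 minus FXRα1 difference. The division genes Bub1, Ncapg, Sgo2a and Cep55 had a larger insert difference with the longer N-terminus, and Ckb, Efhd1 and Rspo4 had a smaller one. Of the 24 measured cell cycle genes 9 were higher in this sense and 0 lower. Of the acute phase genes 8 were lower and 0 higher, and of the amino acid catabolism genes 11 were lower and 1 higher. These list calls did not hold. In all, 2422 genes passed, 1363 upwards and 1059 downwards, so 56.3% were upwards, against 44.3% with median centring.

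The largest interactions upwards were in Bub1 (1.92 ± 0.29), Slc35f2 (1.82 ± 0.17), Ncapg (1.77 ± 0.23), Sgo2a (1.76 ± 0.29) and Cep55 (1.73 ± 0.24), with Bub1 at 1.25 with 16 added to the linear values. The largest downwards were in Ckb (−2.73 ± 0.29), Ramp3 (−2.49 ± 0.17), Efhd1 (−2.15 ± 0.24), Hapln4 (−2.01 ± 0.14) and Rspo4 (−2.01 ± 0.22), with Ramp3 at −1.56 with 16 added. Of the FXR targets, Abcb11 was upwards (1.03 ± 0.18). Pdk4 (−0.64 ± 0.16) and Fga (−0.58 ± 0.11) were downwards. Cyp8b1 (−1.32 ± 0.16) was higher without the insert on the shorter N-terminus and lower without it on the longer one.

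Camera passed 14 lists, 2 upwards and 12 downwards, and none held (adjusted p = 0.0646 to 0.508 with an estimated correlation). The call count was 6 without FXRα2 replicate 1. In the acute phase list, 0 of 22 genes were higher and 8 lower (0 and 9 adjusted over the list alone), with median log2 −0.25, camera adjusted p = 3.26e-06, led by Orm3 (−1.44 ± 0.16), Orm2 (−1.40 ± 0.10) and Apcs (−0.70 ± 0.09). In amino acid catabolism, 1 of 36 genes was higher and 11 lower (1 and 12 adjusted over the list alone), with median log2 −0.14, camera adjusted p = 2.47e-05, including Uroc1 (−1.75 ± 0.19). That median was −0.0581 without FXRα1 replicate 2, −0.23 without FXRα1 replicate 3, −0.0902 without FXRα4 replicate 2 and −0.22 without FXRα4 replicate 3. Among cell cycle genes, 9 of 24 genes were higher and 0 lower (10 and 0 adjusted over the list alone), with median log2 0.39, camera adjusted p = 0.000897. Birc5 (1.33 ± 0.17) and Aurka (1.00 ± 0.18) were higher. In the p53 response, 6 of 18 genes were higher and 2 lower (7 and 2 adjusted over the list alone), with median log2 0.099, camera adjusted p = 0.0251. Fas (1.64 ± 0.15) and Pmaip1 (1.08 ± 0.14) were higher. The p53 call was lost without FXRα1 replicate 2 (0.0888), FXRα2 replicate 1 (0.0589) or FXRα4 replicate 2 (0.0864). In fatty acid oxidation, 2 of 30 genes were higher and 9 lower (2 and 11 adjusted over the list alone), with median log2 −0.14, camera adjusted p = 0.0048. For cholesterol synthesis and uptake, 0 of 20 genes were higher and 5 lower (1 and 9 adjusted over the list alone), with median log2 −0.18, camera adjusted p = 0.00757, and for lipolysis and lipid droplets, 1 of 25 genes was higher and 2 lower (the same adjusted over the list alone), with median log2 −0.15, camera adjusted p = 0.0197.

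**Figure D4:**
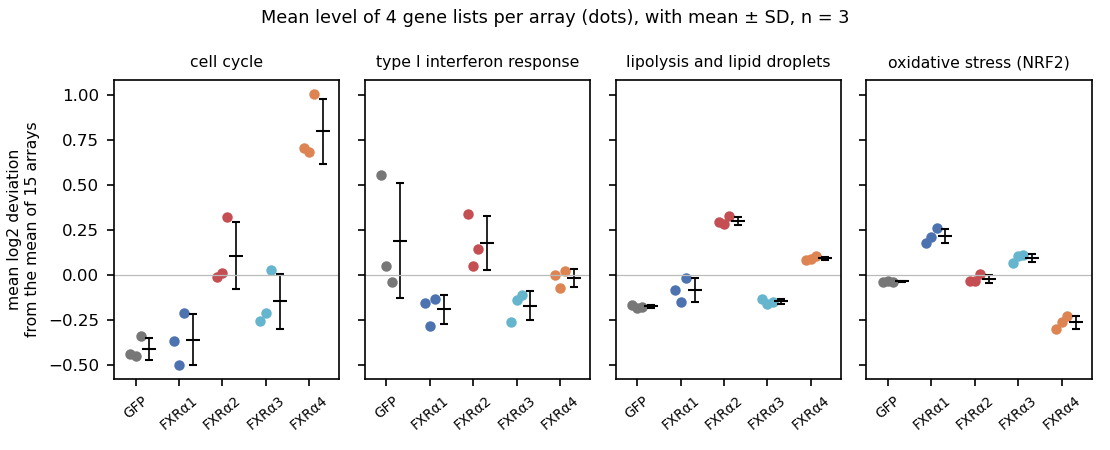
Points give, for each array of the 5 groups (horizontal axis), the mean deviation of a list's genes from their mean over the 15 arrays (log2, vertical axis) for the cell cycle, type I interferon, lipolysis and lipid droplet, and NRF2 lists, with bars at the mean ± SD of 3 arrays. The cell cycle mean was 0.80 with FXRα4 and −0.41 with GFP, and the 3 GFP arrays ranged from −0.037 to 0.557 for the interferon list.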

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

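The tests that weigh explanations for the 3 patterns below, and the splits and divisions of residuals within replicate numbers, were chosen after the results they measure had been seen. The insert difference depended on the N-terminus for 2422 genes by the interaction test of limma. The largest interactions were 1.92 (log2) for Bub1 (1.25 with 16 added to the linear values), 1.82 for Slc35f2, 1.77 for Ncapg, 1.76 for Sgo2a and 1.73 for Cep55, and −2.73 for Ckb, −2.49 for Ramp3 (−1.56 with 16 added), −2.15 for Efhd1, −2.01 for Hapln4 and −2.01 for Rspo4. Lists with an interaction by camera had medians of 0.39 for cell cycle, 0.099 for p53 response, −0.14 for fatty acid oxidation, −0.27 for ketogenesis, −0.15 for lipolysis and lipid droplets, −0.11 for fatty acid and triglyceride synthesis, −0.18 for cholesterol synthesis and uptake and −0.10 for apolipoproteins. The medians were −0.044 for complement and coagulation, −0.25 for acute phase, −0.14 for amino acid catabolism, −0.085 for the mitochondrial respiratory chain, −0.11 for hepatocyte identity and −0.15 for type I interferon response. None of these list calls held with an estimated correlation, and only 6 of the 14 list calls were made without FXRα2 replicate 1. A signal also appeared in the 14338 probe sets with no gene or several, which no comparison used: 356 changed with FXRα1, 1374 with FXRα2, 363 with FXRα3 and 1465 with FXRα4.

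For the 6 comparisons of 3 arrays with 3, the 10 splits are too few for a share under 0.05: the real split was the 1 with the most genes in each, at 2336, 6448, 2647 and 6352 for FXRα1 to FXRα4, 5882 for FXRα2 against FXRα1 and 5561 for FXRα4 against FXRα3, and the highest other split gave 0. Of 100 splits of the 12 isoform arrays, drawn without regard to replicate number, only 1, the real one, gave as many genes for the insert (7182, highest other 2017), the N-terminus (3783, highest other 1062) and the interaction (2422, highest other 1663). These splits put isoform differences into the spread, so they bear on the grouping of the arrays as a whole and not on each of the 3 contrasts alone. Splits within each replicate number, with the number as a block, were tried next and had the same limit: for the interaction, the one that follows the insert gave 5858 genes, against 3343 for the real one. For each contrast, the residuals of a fit without it, with the replicate number as a block, were therefore divided among the 4 isoform arrays of each number, added back and fitted as the real data were. Of 100 of the 108 possible divisions, only the real one gave as many genes for the insert (7866, highest other 1), the N-terminus (4581, highest other 610) and the interaction (3343, highest other 0). If the arrays are independent, a chance division of them is argued against for the grouping as a whole by the splits, and for each of the 3 contrasts by the residuals. The residual counts are those of the fit with the block. In the other divisions the tested difference is part of the spread, which lowers their counts. A chance difference shared by the 3 arrays of a group cannot be excluded, since single arrays were exchanged.

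FXRα2 and FXRα4 changed more genes than FXRα1 and FXRα3. A wider spread between the arrays of FXRα1 and FXRα3 is argued against by the fit itself, which used 1 spread per gene for all 5 groups. The median SD over genes was 0.105 with FXRα1 and 0.073 with FXRα3, against 0.089 with FXRα2 and 0.092 with FXRα4. The fold changes themselves were larger with FXRα2 and FXRα4, with an SD over genes at least 1.85 times as large. Scaling between arrays is argued against as well, since the ratio of the counts was at least 2.18 under every scaling run. If each gene moves one way at every dose, which was not tested, a lower dose of FXRα1 and FXRα3 receptor is argued against for the genes called in opposite directions. These were 11.7% of the genes called in both FXRα1 and FXRα2 (10.9% to 13.8% with the other scalings) and 10.6% for FXRα3 and FXRα4 (11.7% to 12.4%). For the 1509 and 1737 genes called in the same direction in those pairs, a difference in dose and one in activity cannot be told apart. No separate readout of the human transgene is at hand.

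The cell cycle list was higher with FXRα4 at the preset correlation of camera, with 19 of 24 genes higher, but not with an estimated correlation (adjusted p = 0.24). That correlation was estimated without the replicate number as a block, and in each group the mean of the list was highest in replicate 3. More non-parenchymal cells in these cultures cannot be told apart from a change within hepatocytes, because most markers lay near the floor. Of 67 measured markers, 6 were brighter than the median gene, and these had a median change of −0.082 and an upper quartile of 0.72. At most 11.8% of the markers of a cell type were higher (stellate cells and fibroblasts), but dim markers give few calls. Of all 67, 3 were higher and 5 lower. Those higher were Flt4 (2.50), Pdgfra (0.99) and Reln (0.97), named after their values were seen. With FXRα4 the highest level among Col1a1, Col1a2, Col3a1, Pecam1, Lyz2 and Ptprc was 5.19. The median was 5.82 for all genes and 7.86 for the cell cycle genes. None of these 6 transcripts passed against GFP (limma adjusted p = 0.319 to 0.936). A smaller share of hepatocyte RNA stays open as well, since hepatocyte identity genes had a median of 0.25, but of 0.040 with median centring, where 6 were higher and 6 lower. Division or entry into the cell cycle of the hepatocytes themselves was not tested, because RNA of whole cultures does not show which cells it came from.

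The interferon list was lower with FXRα1 and FXRα3 at the preset correlation of camera, with 10 and 9 of 25 genes lower, but not with an estimated correlation (adjusted p = 0.368 and 0.527). Whether a single GFP array with high interferon genes is the whole cause cannot be told apart from a difference between the isoforms and GFP. Without GFP replicate 1 the list passed at the preset correlation (camera adjusted p = 0.00207 and 0.0175), but not with an estimated one (0.382 and 0.576). That array may be part of the cause, since with all arrays the median change was 2.00 and 2.15 times as large as without it. A biological difference between the isoforms and GFP stays open and was not tested further.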

How the results depend on the processing

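Centring on the 75th percentile and centring on the brighter genes were chosen only after the counts with median centring had been seen. For the 584 log2 fold changes of named genes, 6836 of 6932 values under other settings kept their direction and their side of the threshold, 86 lost the call and 10 reversed; with 1 array left out these were 4632, 103 and 5 of 4740. The reversed values were small: Nr1h4 with FXRα1 was −0.046 with quantile normalization, −0.060 with median centring, −0.006 with 75th percentile centring and −0.009 with centring on the brighter genes. Nr0b2 with FXRα1 was 0.001 with quantile normalization and −0.126 to 0.043 with 1 array left out, and Nr1h4 with FXRα3 was −0.040 to 0.014. With median centring, Nr1h4 with FXRα2 was −0.084, Insig2 with FXRα2 −0.006, Fetub −0.022 with FXRα4 and −0.028 for the insert, and Kng1 −0.027 for the insert. Counts of changed genes stayed within 1.5 times under all settings but median centring and the fold minimum. Median centring gave 13162 genes for FXRα2, 11787 for FXRα4, 9200 for FXRα4 against FXRα3, 12326 for the insert and 9483 shared by FXRα2 and FXRα4. It lowers each array by the level of its middle gene, and that level lay where few genes do: 631 genes had a mean between 5.5 and 6, against 2459 between 3.5 and 4 and 1159 between 8 and 8.5. The fold minimum of 1.5 drops smaller changes by construction, and gave 435, 1719, 436 and 1799 genes for FXRα1 to FXRα4, 1356 for FXRα2 against FXRα1, 1347 for FXRα4 against FXRα3, 1165 for the insert, 283 for the N-terminus and 743 for the interaction. With it FXRα2 and FXRα4 shared 1018 genes, FXRα1 and FXRα3 220, and all 4 isoforms 121. Leaving out 1 array gave 1749 to 2789 genes for FXRα1, 5592 to 5941 for FXRα2, 2000 to 2113 for FXRα3 and 5601 to 6081 for FXRα4. Of the 90 list calls, 19 held with an estimated correlation, 81 with fry and all 90 with the replicate number as a block at the preset correlation. The correlation was estimated without that block, so differences shared by arrays of one number enter it. It was not estimated with the block. By comparison the estimated correlation left 3 list calls for FXRα1, 5 for FXRα2, 0 for FXRα3, 0 for FXRα4, 5 for FXRα2 against FXRα1, 0 for FXRα4 against FXRα3, 5 for the insert, 1 for the N-terminus and 0 for the interaction; a list whose genes vary together then counts as fewer independent genes. Fry, which does not compare a list with other genes, called 14 lists for FXRα1, 15 for FXRα4 and 14 for FXRα4 against FXRα3. That last comparison had 2 list calls without the dimmest genes, and the interaction had 9 with quantile normalization; the cause was not tested. Leaving out 1 array moved the interaction's list calls between 6 (without FXRα2 replicate 1) and 16 (without FXRα1 replicate 3). Of the 90 list calls, 81 held with median centring, 85 with 75th percentile centring, 83 with centring on the brighter genes and 76 with quantile normalization, and none reversed. Arrays of one replicate number resembled each other: in 13 of 15 arrays the residuals correlated best with an array of the same number, a hint from the data and not from the labels. As a block, the number raised the counts, to 3072, 7133, 3349 and 7062 for FXRα1 to FXRα4. Dim genes carry mostly background signal, which limits the size of the changes that can be read from them.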

Other observations

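The markers named in this part were chosen after their values had been seen, and no further test was run for it. Drug and xenobiotic metabolism, the 34 measured genes of the detoxifying enzymes, did not pass camera in any of the 9 comparisons. Against GFP, 3 genes were higher and 1 lower with FXRα1 (3 and 2 adjusted over the list alone), 10 and 3 with FXRα2 (11 and 3), 4 and 4 with FXRα3 (5 and 4), and 7 and 10 with FXRα4 (9 and 10). The camera adjusted p was 0.604, 0.15, 0.894 and 0.605 in that order.

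The lists of liver cell types other than hepatocytes did not pass in any comparison either, with camera adjusted p from 0.202 to 0.913 against GFP. Of the 11 cholangiocyte markers, 4 were higher and 1 lower with FXRα1, 4 and 2 with FXRα2, 3 and 1 with FXRα3 (3 and 2 adjusted over the list alone), and 3 and 2 with FXRα4, the others unchanged in count over the list alone. With FXRα4 the median of these markers was −0.020 and their mean 0.43, with Epcam (4.68 ± 0.10) and Sox9 (1.07) higher and Krt19 (−0.93) lower. The 67 measured markers of Kupffer, sinusoidal endothelial and stellate cells, fibroblasts, lymphocytes and neutrophils share 0 genes with another list, and 6 of them were brighter than the median gene. With FXRα4, 3 were higher (Flt4 2.50, Pdgfra 0.99 and Reln 0.97) and 5 lower, and of the 18 lymphocyte and neutrophil markers 0 were higher and 0 lower with any isoform.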
